A study of Homo sapiens with 9 samples.

How the data were processed

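RNA was measured in the human high-grade serous ovarian carcinoma cell line OVCAR-8 after 6 h with DMSO, 0.4 µM or 0.8 µM CDDO-2P-Im, with 3 libraries per group and 9 libraries in all. Per the labels, 500000 cells were treated, RNA was extracted with a PureLink kit, and stranded poly-A libraries were made with a TruSeq mRNA kit. A DMSO content of 1% is recorded for the DMSO libraries only, and none for the CDDO-2P-Im libraries. The submitters' processing notes name cutadapt, HISAT2, StringTie and edgeR without versions, roles or settings, and the genome build and annotation are not given in the sources used here. The deposited table holds FPKM values, 1 column per library, for 60612 entries with 50229 distinct symbols, of which 15458 entries carry a symbol that occurs more than once. Its columns are named control, low and high, and these were matched to DMSO, 0.4 µM and 0.8 µM by the labels.

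The unit was checked on the values. The sums of deposited FPKM differed between libraries, so they had not been scaled to a common total. For 2626 of 8096 genes tested (32.44%), the values multiplied by the summed length of the gene's exons in GENCODE release 29 became decimals of 6 places, within 0.02 of the last place, which is the form of transcript FPKM weighted by transcript length. As a control for matches by accident, 131 of the same genes took this form at that length plus 1 base. A value of 0.0001 stood in for no coverage in the authors' FPKM table and was set to 0. Depth is not stated in the labels. Steps between the lowest values of single-transcript genes put it at 19100000 to 23430000 read pairs per library, an inference from the values, and at this depth an FPKM of 1 in a transcript of 2000 bases rests on 38.2 to 46.9 read pairs.

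Values were analysed as log2(FPKM + 1) in R 4.3.3 with limma 3.58.1 (linear model with 3 groups, empirical Bayes moderation with a trend of the variance with the mean). Log2 fold changes, and counts and simulated changes of 2-fold or 1.41-fold, are on this scale, which understates ratios of low FPKM. The folds given for HMOX1 are ratios of mean FPKM. Genes with an FPKM of at least 1 in at least 3 of the 9 libraries were tested, which left 12071 entries, 131 of them with a repeated symbol. The fit had 6 residual and 2.59 prior degrees of freedom. Each dose was compared with DMSO, and 0.8 µM with 0.4 µM. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p under 0.05. Because the labels do not say whether the 3 libraries of a group come from separate cultures, the p-values measure the spread between these libraries only. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

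Before the data were examined, 27 gene lists with 533 symbols were fixed from general knowledge, of which 26 are reported: NRF2 targets, ATF4 and integrated stress response, endoplasmic reticulum (ER) chaperones and ER-associated degradation, cytosolic heat shock proteins, metallothioneins and zinc response, proteasome subunits, autophagy and lysosome, NF-kB targets, STAT3 targets, interferon-stimulated genes, apoptosis regulators, immediate early genes, G1/S and DNA replication, G2/M and mitosis, homologous recombination and Fanconi genes, sterol synthesis, fatty acid synthesis, hypoxia and glycolysis, YAP and TGF-beta targets, oxidative phosphorylation, ribosomal proteins, mitochondrially encoded mRNAs, ovarian carcinoma and epithelial markers, mesenchymal and fibroblast markers, immune cell markers, and endothelial cell markers. All 533 symbols were found in the table, 1 of them by an older symbol. The 25 lists with at least 4 tested members were compared with all other tested genes by limma camera with a preset inter-gene correlation of 0.01, adjusted over the 25 lists. Camera with a correlation estimated for each list and limma fry were run as alternatives. Members were also counted by the gene test, adjusted over all genes and adjusted over the list alone.

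A rule set at the same time chose the genes named. Among called genes with a symbol, a mean FPKM of at least 5 in the higher group and no overlap between the libraries of both groups, it took the 8 largest rises, the 8 largest falls and up to 4 called members of each list. KEAP1, NFE2L2, HSPA5, STAT3, DDIT3 and HMOX1 were reported in any case, and list members that were not called could be named with their values as examples of members that did not pass. Genes named beyond this rule are said to have been chosen after their values were seen. Some genes taken by the rule, and 1 of the 27 lists, are not reported here and were left out on request, not for their values.

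For the comparison of both doses, which share their 3 DMSO libraries, the correlation, the covariance and the overlap of calls were set beside the mean of 100 simulations with unchanged groups that share controls. Simulated data of the same size and spread had 200 of 12071 genes changed, and the other NRF2 targets raised 1.41-fold. The 200 were drawn from genes with a mean log2(FPKM + 1) of at least 2. Across the 3 comparisons, 69 to 77% of changes of 2-fold and 18 to 33% of changes of 1.41-fold were recovered. Of the calls 4.04 to 6.72% were false, and at most 1 of 25 lists was called without a change in it. The noise was independent between genes, so this rate of list calls does not carry over to lists of correlated genes.

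Alternatives tried were other pseudocounts (0.1 and 5), no filter and a filter at FPKM 5, scaling of each library to a common sum, median-of-ratios scaling, quantile normalization, no variance trend, a fit to the 6 libraries of the groups compared, the replicate number as a block, entries of 1 symbol summed, stricter thresholds, and each library left out in turn. Counts of members of lists and of gene families without each library, and calls gained by lists without each library, were added after the data had been seen. Replicate numbers were not used as pairs, because correlations of deviations from the group means were −0.152 to 0.0487 for libraries of the same number and −0.155 to 0.224 for different numbers, and 0 libraries matched their own number best in both other groups. No library was left out of the comparisons, and no sequencing reads were analysed here.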

Results

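The data are gene-level FPKM from poly-A RNA of OVCAR-8 cells, an established human high-grade serous ovarian carcinoma line, after 6 h with DMSO, 0.4 µM or 0.8 µM CDDO-2P-Im, a synthetic triterpenoid of the oleanane type. Each of the 3 groups has 3 libraries. The steps between low values put the depth at 22590000, 22280000 and 23430000 read pairs for DMSO replicates 1 to 3. It was 21810000, 21950000 and 19100000 for 0.4 µM, and 21570000, 20910000 and 23040000 for 0.8 µM. Between 11032 and 11522 genes per library had an FPKM of at least 1. Mitochondrially encoded transcripts made up 12.95, 15.05 and 17.76% of summed FPKM in DMSO, 8.53, 14.77 and 13.57% at 0.4 µM, and 11.92, 12.82 and 10.65% at 0.8 µM. On the first principal component (51.9% of the variance), the 0.4 µM libraries lay between the DMSO and the 0.8 µM libraries. The second component (12.2%) set 0.4 µM replicate 1, at −36.9, apart from replicates 2 and 3 of its group, at 12.7 and 14.1.

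The first comparison asked which mRNAs of OVCAR-8 cells responded to the lower dose. At 0.4 µM, the clearest change was a rise of NRF2 target mRNAs, which encode enzymes of glutathione synthesis, haem breakdown and quinone reduction. Several cytosolic heat shock mRNAs also rose, among them the inducible HSP70 genes HSPA1A and HSPA1B, which were not called without DMSO replicate 1 or 2. The falls included IL1B, PLAU and IGFBP3, the last 2 not called without some single libraries. No member of the lists of ER chaperones, cell cycle genes or respiratory chain genes passed the gene test.

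At 0.4 µM against DMSO, limma called 109 of 12071 genes, of which 60 rose and 49 fell. Of these, 18 and 16 changed by at least 2-fold on the log2(FPKM + 1) scale. An unadjusted p under 0.05 was found for 1996 genes. The libraries of both groups did not overlap in all 109 called genes, and in 2949 genes tested (24.4%, where chance gives 10%). The share of calls that rose was 55.05%, and it was 62.0% after scaling to a common sum, 42.9% after median-of-ratios scaling and 48.7% after quantile normalization. The median of all genes was 0.04, and 0.09, 0.0075 and 0.02 under these other scalings, and medians of lists at this dose are not relative to it. The count depended on single libraries. It was 31, 31 and 41 without DMSO replicates 1, 2 and 3, and 238, 44 and 58 without 0.4 µM replicates 1, 2 and 3. It was 56 and 51 without 0.8 µM replicates 1 and 3, which enter through the shared spread.

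Of 27 tested NRF2 targets, 13 rose at 0.4 µM and 14 did not pass (20 rose when adjusted over the list alone), with a median log2 fold change of 0.83 (limma camera adjusted p = 1.5e-22, and 0.00372 with an estimated correlation). NRF2 is the transcription factor that KEAP1 holds at low levels until electrophiles modify KEAP1. HMOX1, which encodes haem oxygenase 1, rose 67.1-fold, from 9.24 ± 1.88 to 620 ± 166 FPKM (mean ± SD, n = 3 per group here and below; limma adjusted p = 2.36e-05). The cystine transporter gene SLC7A11 rose from 0.848 ± 0.242 to 13.7 ± 2.82 FPKM (adjusted p = 7.58e-05), and GCLM, a subunit of the enzyme that starts glutathione synthesis, from 10.9 ± 0.647 to 68.3 ± 8.22 FPKM (adjusted p = 2.36e-05). NQO1 rose from 57.0 ± 5.10 to 149 ± 23.1 FPKM and SRXN1 from 20.9 ± 1.06 to 53.6 ± 3.82 FPKM (adjusted p = 0.0024 and 0.000171). The genes of the pathway itself did not pass. NFE2L2, which encodes NRF2, went from 10.7 ± 0.353 to 13.7 ± 1.00 FPKM (limma adjusted p = 0.623) and KEAP1 from 25.5 ± 2.0 to 31.6 ± 1.56 FPKM (adjusted p = 0.168). The spread in this test is shared with the 0.8 µM libraries, which differed widely for NFE2L2. Its p-value at 0.4 µM is therefore no evidence that NFE2L2 stayed unchanged. TXNRD1 went from 17.2 to a mean of 185 FPKM without passing (adjusted p = 0.0697). This gene, chosen after its values were seen, had 44.9 FPKM in 0.4 µM replicate 1 against 244 and 265 in the others.

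Of 20 cytosolic heat shock genes, 6 rose and 14 did not pass (14 rose and 1 fell when adjusted over the list alone; median 0.41, limma camera adjusted p = 2.57e-10, adjusted p = 0.0509 with an estimated correlation). The count was 3 without DMSO replicate 1 or without DMSO replicate 2. HSPH1 rose from 16.9 ± 1.87 to 34.4 ± 2.20 FPKM and HSPA4L from 5.26 ± 0.291 to 9.78 ± 0.455 FPKM (limma adjusted p = 0.00452 and 0.00269). HSPA1A (175 ± 14.7 to 622 ± 225 FPKM, adjusted p = 0.0115) and HSPA1B (159 ± 18 to 500 ± 148 FPKM, adjusted p = 0.0106) lost their calls without DMSO replicate 1 or 2 (adjusted p up to 0.0695 and 0.0681). The split of reads between these near-identical genes is uncertain. DDIT3 and HSPA5, markers of ER stress, did not pass (9.60 ± 1.37 to 9.77 ± 0.306 and 148 ± 9.86 to 162 ± 3.78 FPKM, adjusted p = 0.938 and 0.532). Of 23 ER chaperone and degradation genes, limma called 0, and 0 when adjusted over the list alone, while 7 had an unadjusted p under 0.05 (median 0.14, camera adjusted p = 0.0722). Without DMSO replicate 2 that list was called (0.21, adjusted p = 0.0114).

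Of 27 ATF4 targets 4 rose at 0.4 µM (15 when adjusted over the list alone; median 0.37, limma camera adjusted p = 8.32e-09, adjusted p = 0.252 with an estimated correlation). These were SLC3A2 (29.8 ± 3.59 to 62.2 ± 8.60 FPKM), SLC7A5, PPP1R15A and SESN2. The gene calls were fragile, with a count of 0 without any 1 DMSO library or 0.4 µM replicate 2. It was 1 without 0.4 µM replicate 3 or 0.8 µM replicate 2 or 3, and 2 without 0.8 µM replicate 1 or after median-of-ratios scaling. Of 19 autophagy and lysosome genes only SQSTM1 rose, from 52.7 ± 4.51 to 166 ± 2.32 FPKM (limma adjusted p = 6.15e-05; list median 0.15, camera adjusted p = 0.0559, and 0.0478 without 0.4 µM replicate 3). It encodes the autophagy receptor p62, which is also an NRF2 target. Of 13 hypoxia and glycolysis genes NDRG1 alone rose (4.10 ± 0.285 to 8.94 ± 0.812 FPKM, adjusted p = 0.0146, up to 0.0765 without DMSO replicate 1 or 2). Adjusted over the list alone 1 rose and 1 fell (median 0.07, and 0.25 after scaling to a common sum, camera adjusted p = 0.672). The zinc exporter gene SLC30A1, chosen after its values were seen, was the single riser among 6 metallothionein and zinc genes (log2 fold change 0.79, adjusted p = 0.0363; list median −0.23, and −0.11 after quantile normalization, mean −0.04, camera adjusted p = 0.305). Only without 0.4 µM replicate 1 or 0.8 µM replicate 2 was it still called, so that 0 of the 6 were called without each of the other libraries.

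Among the largest falls at 0.4 µM were KRTAP2-3 (18.7 ± 3.91 to 3.41 ± 1.5 FPKM), PLAU, which encodes urokinase (27.8 ± 0.834 to 11.6 ± 2.96 FPKM), and TRIM55 (7.89 ± 1.29 to 2.15 ± 0.445 FPKM). IGFBP3 (56.4 ± 13.4 to 22.9 ± 4.98 FPKM) and SCG5 (6.23 ± 0.321 to 2.11 ± 0.813 FPKM) also fell. Limma no longer called KRTAP2-3 without DMSO replicate 1 (adjusted p = 0.0563) or PLAU without any 1 DMSO library (up to 0.0886). The call of SCG5 was lost without any 1 DMSO library or 0.4 µM replicate 3 (adjusted p up to 0.103), and that of IGFBP3 without any library except DMSO replicate 1 (up to 0.152). SNORD58B, C1GALT1C1 and ZNF672 also fell and are taken up with the comparison of doses. Of 15 NF-kB targets IL1B fell (4.75 ± 0.808 to 0.756 ± 0.414 FPKM; chosen after its values were seen) and 14 did not pass (median −0.41, limma camera adjusted p = 1.21e-05, adjusted p = 0.508 with an estimated correlation). The median of this list was −0.67 without DMSO replicate 2, −0.64 without 0.4 µM replicate 3 and −0.14 without 0.4 µM replicate 1. Of 8 ovarian carcinoma and epithelial markers 0 were called by limma over all genes, 5 had an unadjusted p under 0.05 and 4 fell when adjusted over the list alone. The list was called (median −0.42, camera adjusted p = 1.83e-06, and 0.0414 with an estimated correlation).

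A further 5 lists were called by limma camera at 0.4 µM with 0 members called by limma, although 0 to 7 of their members had an unadjusted p under 0.05. None of these list calls held with an estimated correlation. G2/M genes lay higher (median 0.19, adjusted p = 0.00246, adjusted p = 0.508 with an estimated correlation; 1 of 25 rose when adjusted over the list alone). Lower were the 30 ribosomal protein genes (median −0.13, adjusted p = 0.0024, adjusted p = 0.645 with an estimated correlation), the 30 oxidative phosphorylation genes (−0.10, 0.00516, and 0.645 with an estimated correlation). The same held for the 22 sterol synthesis genes (−0.18, 0.0078, and 0.645 with an estimated correlation) and the 11 mitochondrially encoded mRNAs (−0.51, 0.000129, and 0.508 with an estimated correlation). The ribosomal protein call ended without 0.4 µM replicate 2 or 3 (adjusted p = 0.0949 and 0.13). That of oxidative phosphorylation ended without DMSO replicate 1 (0.0536) and 0.4 µM replicates 2 and 3 (0.09 and 0.192). The sterol call ended without DMSO replicates 1 and 3 (0.051 and 0.0737) and without 0.4 µM replicate 1 (0.931). These small medians depended on single libraries. That of ribosomal proteins was −0.25, −0.05 and −0.06 without 0.4 µM replicates 1, 2 and 3, and that of oxidative phosphorylation −0.16 and −0.05 without 0.4 µM replicates 1 and 2 and −0.06 without DMSO replicate 1. For sterol synthesis it was −0.11 and −0.31 without DMSO replicates 1 and 2 and −0.05 without 0.4 µM replicate 1, and for the mitochondrial mRNAs −0.21 without 0.4 µM replicate 1. After quantile normalization neither ribosomal proteins (median −0.03) nor oxidative phosphorylation (−0.05) was called.

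The remaining lists were not called at 0.4 µM. Limma camera gave an adjusted p of 0.28 for proteasome subunits (median 0.08). It was 0.305 for interferon-stimulated genes (0.12), immediate early genes (0.12), G1/S and DNA replication (0.09) and homologous recombination and Fanconi genes (0.09). It was 0.437 for fatty acid synthesis (−0.08) and 0.704 for mesenchymal markers (−0.07). For STAT3 targets (median 0.02, mean −0.03, adjusted p = 0.648), apoptosis regulators (0.09, 0.0090, 0.753) and YAP and TGF-beta targets (0.0032, −0.08, 0.368) the test pointed down while the median was positive. Leaving out 1 library led to a call for immediate early genes without 0.4 µM replicate 1 (median 0.21, adjusted p = 0.0478), and for proteasome subunits without DMSO replicate 1 (0.11, 0.0293) or 0.4 µM replicate 3 (0.12, 0.0446). In these lists limma called 0 genes over all genes tested, although 1 to 6 members of each had an unadjusted p under 0.05. Adjusted over the list alone, 2 STAT3 targets and 3 immediate early genes rose. In the same way 1 apoptosis regulator rose and 2 fell, and 1 YAP target rose and 2 fell. STAT3 did not pass (4.92 ± 0.458 to 4.87 ± 0.608 FPKM, limma adjusted p = 0.96). The immune and endothelial markers had 1 and 2 tested members, of which limma called 0, and 0 at an unadjusted p under 0.05.

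**Figure D1:**
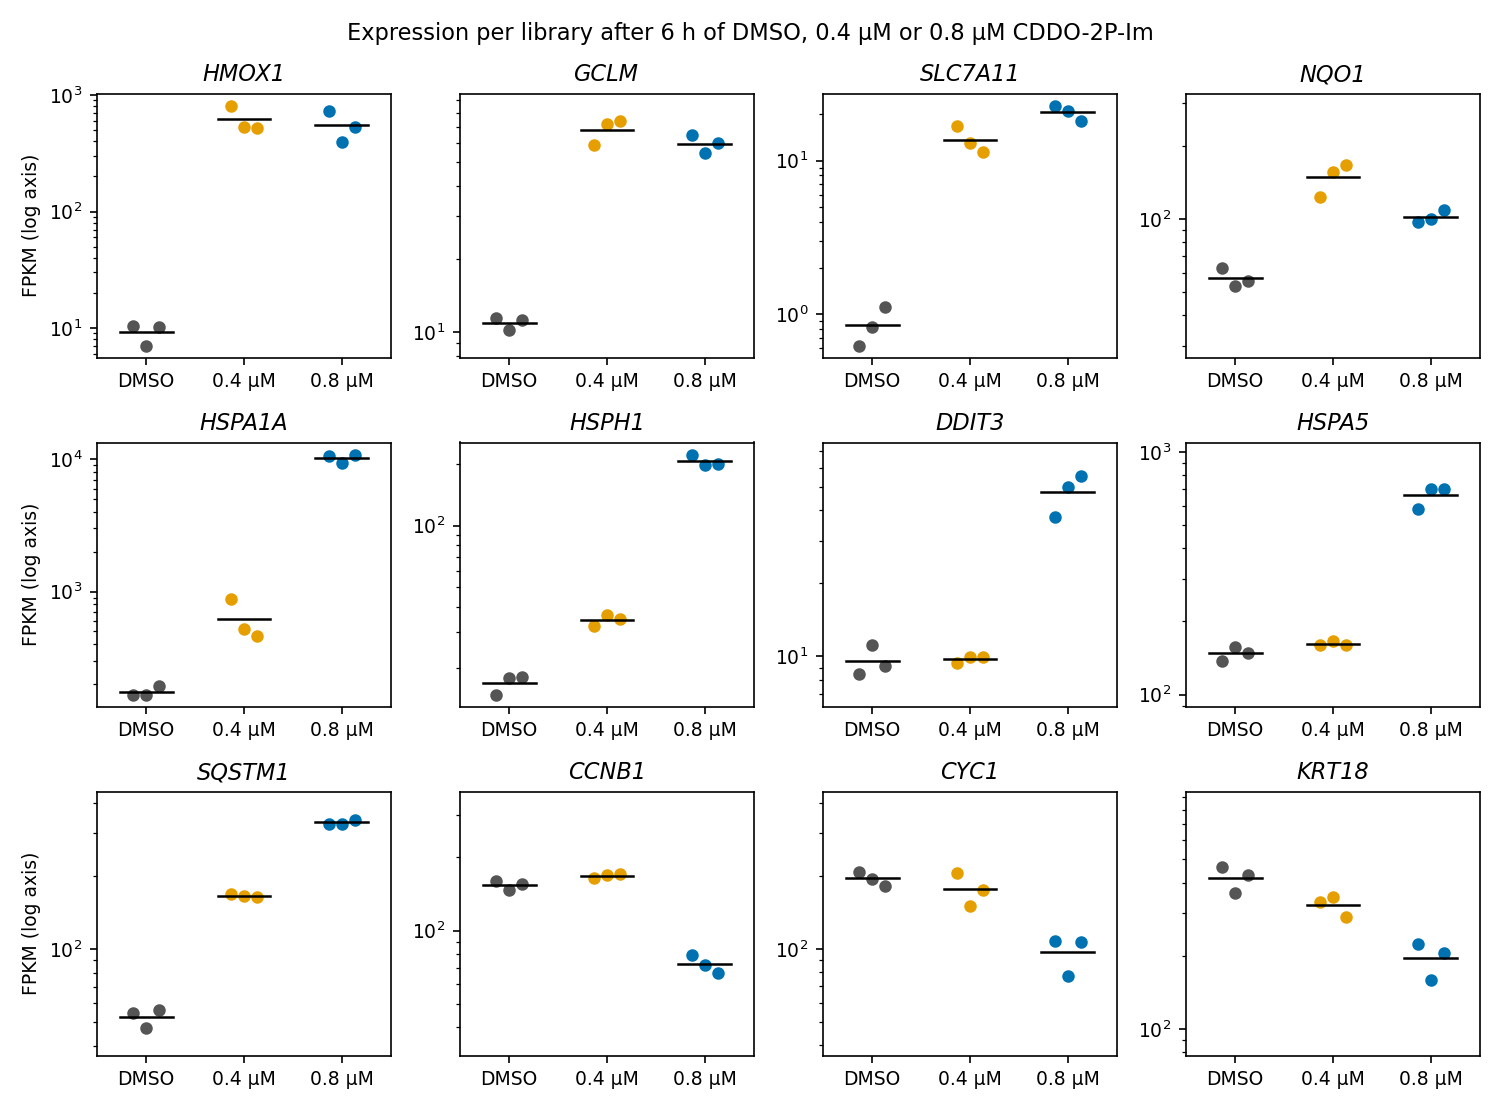
FPKM of 12 genes in each library on a logarithmic axis, grouped as DMSO, 0.4 µM and 0.8 µM CDDO-2P-Im; each point is a library and the black line is the group mean. HMOX1, GCLM and SLC7A11 were already high at 0.4 µM, while HSPA1A, DDIT3 and HSPA5 reached their highest values at 0.8 µM and CCNB1, CYC1 and KRT18 their lowest.

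The comparison of 0.8 µM with DMSO asked how far the response extends at the higher dose. Here nearly all cytosolic heat shock mRNAs rose, together with most of the listed ER chaperones and targets of ATF4, the transcription factor of the integrated stress response. The median change of NRF2 targets in the deposited values was 0.83 at both doses. Most of the listed genes of mitosis fell, as did most ovarian and epithelial markers and 5 of 11 mRNAs encoded by mitochondrial DNA. Of the respiratory chain genes 23 of 30 fell as deposited, but 12 after scaling to a common sum and 13 after quantile normalization. The mRNAs of several apoptosis regulators changed in both directions.

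Limma called 5794 of 12071 genes at 0.8 µM, with 2604 rising and 3190 falling, 538 and 475 of them by at least 2-fold on the log2(FPKM + 1) scale. An unadjusted p under 0.05 was found for 6696. Libraries of both groups did not overlap in 7474 genes (61.9%, where chance gives 10%). Leaving out any 1 library gave 4452 to 6494 calls. The direction of small changes depends on scaling: the median of all genes was −0.07, and scaling to a common sum moved it by 0.143 on the log2 scale, to 0.08. Accordingly 44.9% of calls rose as deposited, 60.3% after scaling to a common sum, 53.2% after median-of-ratios scaling and 49.2% after quantile normalization. Medians of lists in the paragraphs that follow on this comparison are therefore given relative to the median of all genes.

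Cytosolic heat shock genes showed the largest shift of any list at this dose: 19 of 20 rose (19 when adjusted over the list alone) and CRYAB did not pass (9.31 ± 0.716 to 8.84 ± 1.03 FPKM). The relative median was 1.83 (limma camera adjusted p = 2.63e-15, adjusted p = 0.0542 with an estimated correlation), and the count was 19 without each library in turn. HSPA6, an HSP70 gene that is nearly silent in unstressed cells, rose from 0.563 ± 0.247 to 406 ± 94.8 FPKM (limma adjusted p = 8.96e-07). HSPA1A rose from 175 ± 14.7 to 10285 ± 840 FPKM and HSPA1B from 159 ± 18 to 8443 ± 782 FPKM (adjusted p = 1.5e-06 and 9.85e-07). HSPH1, which encodes HSP110, rose from 16.9 ± 1.87 to 207 ± 14.1 FPKM (adjusted p = 5.63e-07). Outside the list, the co-chaperone gene DNAJA4 rose from 1.35 ± 0.0810 to 44.3 ± 1.51 FPKM and the HSPA6 paralog HSPA7 from 0.0244 ± 0.00897 to 26.6 ± 14.1 FPKM. Reads of HSPA6 and HSPA7, like those of HSPA1A and HSPA1B, are hard to separate, so the level of each is uncertain.

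Of 23 ER chaperone and degradation genes 21 rose (21 when adjusted over the list alone), with a relative median of 0.95 (limma camera adjusted p = 4.49e-10, adjusted p = 0.142 with an estimated correlation). HSPA5, which encodes the ER chaperone BiP, rose from 148 ± 9.86 to 663 ± 72.2 FPKM (limma adjusted p = 4.61e-06), DNAJB9 from 1.78 ± 0.165 to 15.5 ± 1.28 FPKM and HERPUD1 from 8.48 ± 0.653 to 44.1 ± 6.33 FPKM. CRELD2 (4.89 ± 0.623 to 4.83 ± 0.0799 FPKM) and SEC61B (70.7 ± 4.39 to 77.9 ± 10.4 FPKM) did not pass. Of 27 ATF4 targets 24 rose (24 when adjusted over the list alone), with a relative median of 1.07 (camera adjusted p = 4.49e-10, adjusted p = 0.142 with an estimated correlation). PPP1R15A, which encodes the phosphatase subunit GADD34, rose from 44.3 ± 5.11 to 356 ± 49.3 FPKM (adjusted p = 2.78e-06), SLC3A2 from 29.8 ± 3.59 to 210 ± 33.4 FPKM, DDIT4 from 2.69 ± 0.0974 to 19.9 ± 3.62 FPKM and SESN2 from 4.56 ± 0.0710 to 29.7 ± 2.58 FPKM. DDIT3, which encodes the stress factor CHOP, rose from 9.60 ± 1.37 to 47.7 ± 9.20 FPKM (adjusted p = 3.05e-05). CEBPB (19.3 ± 1.00 to 24.0 ± 0.743 FPKM), PCK2 (18.8 ± 2.75 to 14.4 ± 2.93 FPKM) and STC2 (15.5 ± 1.66 to 14 ± 1.79 FPKM) did not pass.

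Of 27 NRF2 targets 16 rose, 2 fell and 9 did not pass (17 and 2 when adjusted over the list alone; relative median 0.89, limma camera adjusted p = 1.33e-06, adjusted p = 0.0607 with an estimated correlation). HMOX1 rose 59.7-fold, to 551 ± 168 FPKM (limma adjusted p = 3.84e-06), SLC7A11 to 20.6 ± 2.43 FPKM, GCLM to 59.7 ± 5.0 FPKM and the thioredoxin reductase gene TXNRD1 from 17.2 ± 0.272 to 129 ± 40.2 FPKM (adjusted p = 0.00542). The 2 that fell, chosen after their values were seen, were TXN and TALDO1 (log2 fold changes of −0.41 and −0.33). None of the list fell under any of the 3 other scalings, nor without DMSO replicate 1 or 0.8 µM replicate 2, and 1 fell without 0.8 µM replicate 1 or 3. KEAP1 did not pass (22.4 ± 1.0 FPKM, adjusted p = 0.114), nor did NFE2L2 (14.7 ± 6.87 FPKM, adjusted p = 0.459). For NFE2L2, 0.8 µM replicate 2 had 6.84 FPKM against 19.7 and 17.4 in the others, and without that library the gene was called (log2 fold change 0.74, limma adjusted p = 0.00175).

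Of 19 autophagy and lysosome genes 10 rose (10 when adjusted over the list alone; relative median 0.47, limma camera adjusted p = 0.00674, adjusted p = 0.124 with an estimated correlation). SQSTM1 reached 333 ± 7.35 FPKM from 52.7 ± 4.51 (limma adjusted p = 8.64e-07), MAP1LC3B 69.4 ± 9.54 from 19.8 ± 1.0 and the kinase gene ULK1 6.47 ± 1.27 from 1.88 ± 0.211 FPKM. Proteasome subunits went both ways. Of 31, 7 rose, led by PSMD12 (21.6 ± 1.75 to 33.7 ± 1.61 FPKM), and 8 fell, led by PSMC5 (53.6 ± 5.02 to 34.0 ± 5.65 FPKM). The balance depended on scaling, with 9 rises and 3 falls after scaling to a common sum, 9 and 4 after median-of-ratios scaling and 11 and 2 after quantile normalization. Their relative median was −0.12, but 0.14 after quantile normalization (camera adjusted p = 0.851). The 8 falls became 4 without DMSO replicate 1, DMSO replicate 2 or 0.8 µM replicate 2, and 13 without 0.4 µM replicate 1. Among 6 metallothionein and zinc genes, SLC30A1 rose from 2.41 ± 0.288 to 11.1 ± 1.92 FPKM, while MT2A and MT1E fell from 1626 ± 85.1 to 1098 ± 134 and from 683 ± 44.0 to 467 ± 68.5 FPKM. The relative median of the list was −0.24 (camera adjusted p = 0.596). MT2A was not called after quantile normalization, and reads shared between metallothionein genes leave their levels uncertain.

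Immediate early genes are switched on within minutes of many stimuli. Of 20, 10 rose and FOSL1, chosen after its values were seen, fell (11 and 2 when adjusted over the list alone; relative median 0.56, limma camera adjusted p = 0.0133, adjusted p = 0.548 with an estimated correlation). ZFP36 rose from 2.37 ± 0.384 to 9.74 ± 0.745 FPKM, EGR1 from 7.67 ± 2.74 to 25.1 ± 1.87 FPKM and JUNB from 22.9 ± 4.57 to 55.2 ± 5.67 FPKM (limma adjusted p = 0.000107, 0.000716 and 0.000893). The single fall became 3 without DMSO replicate 2 or 0.4 µM replicate 1. Of 15 NF-kB targets 2 rose and 4 fell, with IL6 going from 6.83 ± 1.66 to 0.944 ± 0.213 FPKM and NFKBIE from 10.7 ± 1.57 to 18.6 ± 0.708 FPKM (relative median −0.17, camera adjusted p = 0.596), and after scaling to a common sum 3 rose and 7 fell. IRF1 also rose and IL1B, BCL2A1 and CXCL2 also fell, all chosen after their values were seen. Among 14 STAT3 targets 6 rose, among them PIM1 (3.53 ± 0.392 to 12.5 ± 0.787 FPKM), and 4 fell, among them CCND1 (122 ± 11.8 to 55.9 ± 8.14 FPKM; relative median 0.32, camera adjusted p = 0.362). STAT3 itself did not pass (4.92 ± 0.458 to 5.66 ± 0.553 FPKM, adjusted p = 0.245).

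Interferon-stimulated genes were not called as a list (5 of 15 rose and 2 fell; relative median 0.29, limma camera adjusted p = 0.166). IFIT3 rose from 2.39 ± 0.0717 to 6.00 ± 0.380 FPKM. The 2 falls, PSMB9 and IFI27 (chosen after their values were seen), became 0 without DMSO replicate 1, DMSO replicate 2, 0.8 µM replicate 1 or 0.8 µM replicate 2, and 1 without DMSO replicate 3 or 0.4 µM replicate 3. They became 0 after scaling to a common sum and 1 after median-of-ratios scaling. Of 14 YAP and TGF-beta targets 5 rose and 6 fell (relative median −0.13, camera adjusted p = 0.534). ANKRD1 fell from 296 ± 34.5 to 76.9 ± 4.89 FPKM (limma adjusted p = 2.42e-05) and AXL from 81.0 ± 8.01 to 33.8 ± 4.49 FPKM. The 5 rises became 3 without DMSO replicate 1, DMSO replicate 2, 0.8 µM replicate 1 or 0.8 µM replicate 3, and 2 without 0.8 µM replicate 2.

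Of 20 apoptosis regulators 7 rose and 5 fell (8 and 5 when adjusted over the list alone; relative median 0.18, but 0.07 after scaling to a common sum; limma camera adjusted p = 0.303). The rises included mRNAs of BH3-only proteins that promote cell death: BCL2L11, which encodes BIM (0.545 ± 0.266 to 6.83 ± 2.92 FPKM, limma adjusted p = 0.000709), BIK (2.88 ± 0.250 to 10.1 ± 2.40 FPKM) and PMAIP1, which encodes NOXA (9.75 ± 1.75 to 25.7 ± 2.02 FPKM). The falls, chosen after their values were seen, were BCL2L1, CFLAR, BAX, XIAP and BAD, and their count was 3 without DMSO replicate 1, DMSO replicate 3 or 0.8 µM replicate 2.

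Mitotic genes fell. Of 25 G2/M genes 17 were lower and 8 did not pass (17 fell when adjusted over the list alone). Under the other scalings 13 to 16 fell and 1 rose. The relative median was −0.53, and −0.39 after quantile normalization (limma camera adjusted p = 2.58e-05, adjusted p = 0.291 with an estimated correlation). CDC20 fell from 160 ± 11.6 to 66.9 ± 6.06 FPKM, CCNB1, which encodes cyclin B1, from 154 ± 6.94 to 72.9 ± 6.28 FPKM (limma adjusted p = 6.35e-05 for both) and PLK1 from 30.9 ± 3.54 to 13.9 ± 1.91 FPKM. Of 23 G1/S genes 2 rose and 7 fell, with UNG at 64.0 ± 0.736 and 29.1 ± 4.72 FPKM and GINS1 at 8.42 ± 0.400 and 3.84 ± 0.713 FPKM in DMSO and at 0.8 µM (relative median −0.15, but 0.03 after quantile normalization; camera adjusted p = 0.113). The 7 falls became 4 without DMSO replicate 3, 3 after scaling to a common sum and 5 under either of the other scalings. The 2 that rose were CDC6 (13.1 ± 3.63 to 22.6 ± 4.50 FPKM) and SLBP, the latter chosen after its values were seen. CDC6 lost its call without DMSO replicate 2 or 3 or 0.8 µM replicate 1 or 3 (adjusted p up to 0.0697), and the list had 1 rise without DMSO replicate 2 or 3 or 0.8 µM replicate 1. Of 14 homologous recombination and Fanconi genes 5 fell, led by RAD54L (7.04 ± 0.115 to 3.96 ± 0.420 FPKM), and 3 fell when adjusted over the list alone (relative median −0.21, camera adjusted p = 0.0736, and 0.0459 without 0.8 µM replicate 2). The count over all genes was 3 without DMSO replicate 2, DMSO replicate 3 or 0.8 µM replicate 3, 2 after scaling to a common sum, 4 after median-of-ratios scaling and 7 after quantile normalization.

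Genes of the respiratory chain fell as a group. Of 30 oxidative phosphorylation genes 23 were lower and 7 did not pass (23 fell when adjusted over the list alone; relative median −0.38, limma camera adjusted p = 3.33e-06, adjusted p = 0.407 with an estimated correlation). Under the other scalings 12 to 18 of them fell. CYC1 went from 195 ± 13.2 to 97.5 ± 17.3 FPKM, NDUFV2 from 71.8 ± 0.0378 to 38.7 ± 1.56 FPKM and ATP5MC1 from 34.5 ± 1.89 to 17.2 ± 1.78 FPKM (limma adjusted p = 0.0012, 0.000116 and 0.00152). Of 11 mitochondrially encoded mRNAs 5 fell, among them MT-CO3 (3671 ± 448 to 852 ± 293 FPKM) and MT-ND3 (3562 ± 266 to 974 ± 169 FPKM), with a relative median of −0.87 (camera adjusted p = 0.0101, adjusted p = 0.556 with an estimated correlation). The count was 9 without 0.4 µM replicate 1. The mitochondrial pseudogenes MTCO1P12, MTND1P23 and MTCO3P12 were among the largest falls, and their reads cannot be told from those of their parent genes. Ribosomal protein genes fell in 14 of 30 cases (11 when adjusted over the list alone; relative median −0.30, camera adjusted p = 0.000608, adjusted p = 0.556 with an estimated correlation). Under each of the 3 other scalings 5 fell, and the relative median was −0.02 after quantile normalization, where the list was not called. The count was 6 without DMSO replicate 1, DMSO replicate 2 or 0.8 µM replicate 2, 5 without 0.8 µM replicate 1 and 22 without 0.4 µM replicate 1. RPL32 went from 368 ± 60.9 to 221 ± 15.1 FPKM.

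Lipid and glucose genes moved in both directions. Of 22 sterol synthesis genes 3 rose and 7 fell (relative median −0.15, limma camera adjusted p = 0.362), with ACAT2 at 53.4 ± 6.34 and 26.8 ± 3.86 FPKM in DMSO and at 0.8 µM. The 3 rises became 1 without DMSO replicate 2 or 0.8 µM replicate 2. ELOVL5 rose (45.7 ± 1.62 to 105 ± 7.19 FPKM) and ELOVL6 fell (6.34 ± 0.283 to 3.45 ± 0.466 FPKM; adjusted p = 0.0516 without 0.8 µM replicate 2) among 10 fatty acid synthesis genes (relative median −0.09, and −0.03 after quantile normalization, camera adjusted p = 0.794). Without 0.8 µM replicate 1 there were 2 falls in that list. Of 13 hypoxia and glycolysis genes 5 rose and 5 fell. NDRG1 went from 4.10 ± 0.285 to 19.1 ± 3.22 FPKM and ENO1 from 564 ± 23.4 to 334 ± 67.1 FPKM (camera adjusted p = 0.534). The relative median was 0.04, but 0.25 after scaling to a common sum and −0.05 after quantile normalization, where 6 rose and 3 fell.

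Ovarian carcinoma and epithelial markers fell in 7 of 8 cases, and FOLR1 (7.59 ± 0.502 to 6.08 ± 0.951 FPKM) did not pass (7 when adjusted over the list alone; relative median −0.81, limma camera adjusted p = 0.00186, adjusted p = 0.124 with an estimated correlation). The lineage factor gene PAX8 fell from 11.3 ± 1.34 to 4.02 ± 0.864 FPKM, KRT7 from 169 ± 3.91 to 77.2 ± 18.4 FPKM and KRT18 from 418 ± 52.5 to 196 ± 33.7 FPKM (limma adjusted p = 0.000295, 0.000489 and 0.000695). Among 6 mesenchymal markers COL1A1 (43.2 ± 9.33 to 15.1 ± 3.42 FPKM), FN1 and VIM fell (relative median −0.32, camera adjusted p = 0.362). After scaling to a common sum the relative median was −0.08, with 1 rise and 4 falls, and after quantile normalization it was −0.19. FN1 lost its call without DMSO replicate 2 (adjusted p = 0.0506). The endothelial marker EGFL7 fell (29 ± 2.48 to 18.6 ± 2.77 FPKM), and the tested immune marker, CD68, did not pass (8.13 ± 2.22 to 12.3 ± 4.47 FPKM). Large falls outside the lists included SERPINB2 (29.3 ± 2.96 to 1.49 ± 0.148 FPKM), the WNT inhibitor gene DKK1 (54.0 ± 4.48 to 4.71 ± 0.351 FPKM), the tissue factor gene F3 (177 ± 7.90 to 26.1 ± 4.20 FPKM), INSYN2B and KRTAP2-3. AL671762 was listed at 0 in all DMSO libraries, at 0, 0 and 8.34 FPKM at 0.4 µM and at 65.9, 97.8 and 94.2 FPKM at 0.8 µM. MIR22 also rose, although precursors of small RNAs are poorly measured in poly-A libraries, which leaves its value uncertain.

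**Figure D2:**
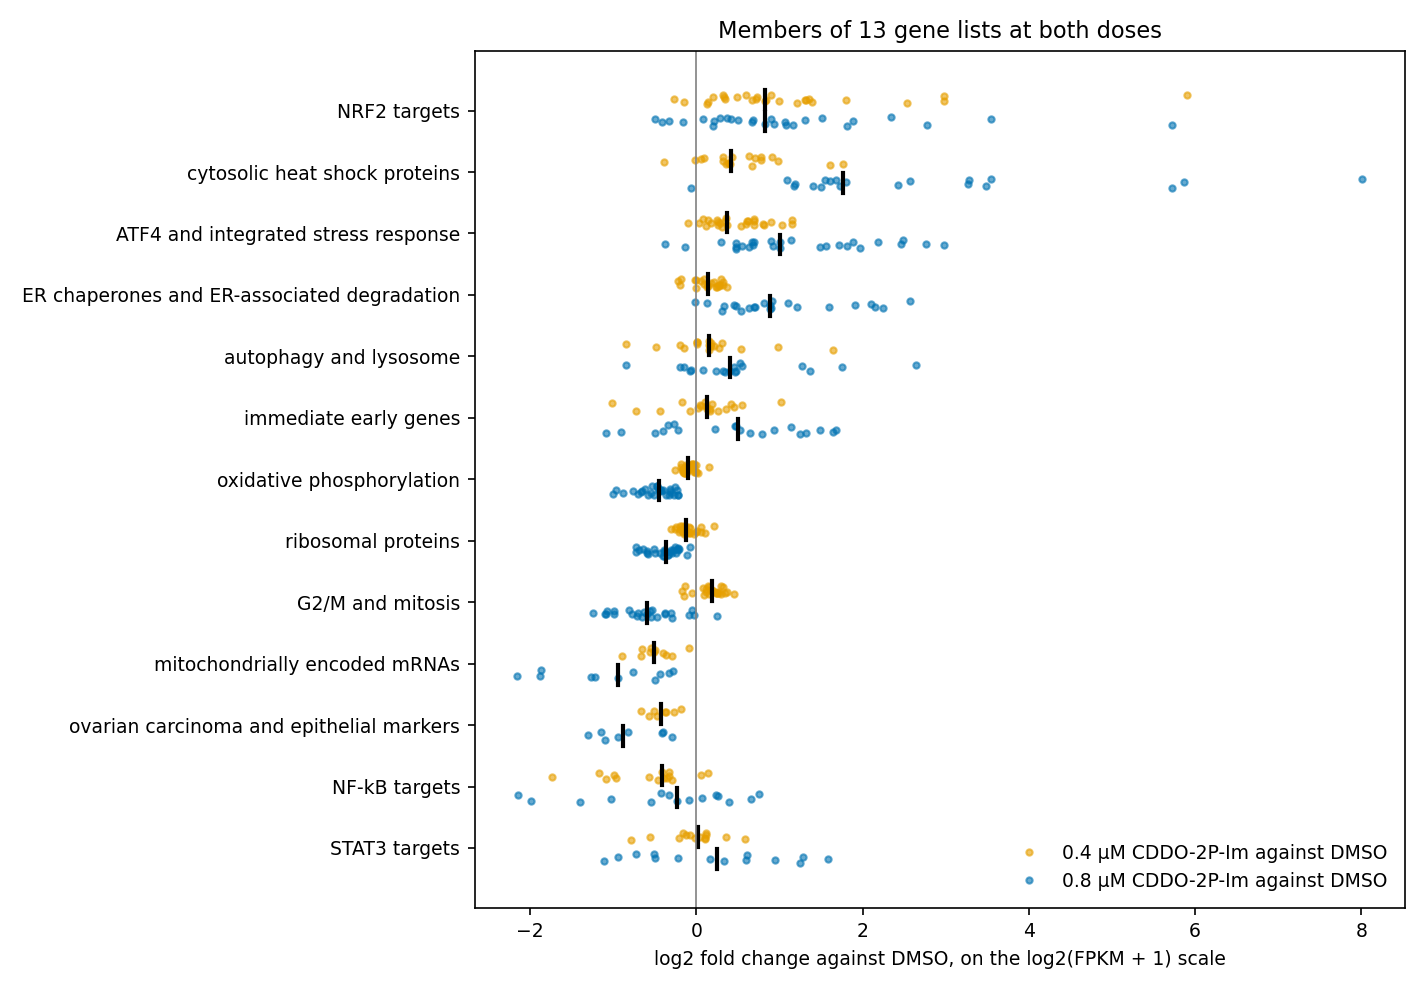
Log2 fold change against DMSO of the tested members of 13 gene lists at 0.4 µM and 0.8 µM; each point is a gene and the black bar is the list median, not relative to all genes. NRF2 targets had a median of 0.83 at both doses, while heat shock genes went from 0.41 to 1.76 and G2/M genes from 0.19 to −0.59.

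The direct comparison of 0.8 µM with 0.4 µM asked which mRNAs depended on dose. Most of the listed heat shock and ER mRNAs and 15 of 27 ATF4 targets were higher at 0.8 µM, and 20 of 25 mRNAs of mitosis were lower. The NRF2 targets went both ways between the doses, with 4 of 27 higher and 6 lower and no net shift called. Limma called 4212 of 12071 genes, 1659 higher and 2553 lower at 0.8 µM, 288 and 147 of them by at least 2-fold on the log2(FPKM + 1) scale. For 5506 genes the unadjusted p was under 0.05, and libraries did not overlap in 5906 genes (48.9%, where chance gives 10%). The count was 2713 without 0.8 µM replicate 2. The share that rose was 39.4%, against 54.5% after scaling to a common sum, 57.1% after median-of-ratios scaling and 48.9% after quantile normalization. The median of all genes was −0.10, and −0.0036, −0.0012 and −0.05 under these scalings in turn. List medians in this comparison are given relative to it unless stated.

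Cytosolic heat shock genes were higher in 19 of 20 cases (20 when adjusted over the list alone; relative median 1.5, limma camera adjusted p = 2.36e-20, and 0.0259 with an estimated correlation). DNAJB1, which encodes HSP40, went from 53.4 ± 5.92 FPKM at 0.4 µM to 384 ± 74.0 FPKM at 0.8 µM (limma adjusted p = 1.93e-05), HSPA6 from 2.04 ± 0.996 to 406 ± 94.8 FPKM and HSPA1B from 500 ± 148 to 8443 ± 782 FPKM. Of 23 ER genes 19 were higher (19 when adjusted over the list alone; relative median 0.75, camera adjusted p = 8e-13, adjusted p = 0.168 with an estimated correlation), with HSPA5 at 162 ± 3.78 and 663 ± 72.2 FPKM and DNAJB9 at 2.21 ± 0.0588 and 15.5 ± 1.28 FPKM. Of 27 ATF4 targets 15 were higher (21 higher and 1 lower when adjusted over the list alone; relative median 0.57, camera adjusted p = 6.95e-09, adjusted p = 0.211 with an estimated correlation), led by PPP1R15A (72.3 ± 4.40 to 356 ± 49.3 FPKM) and DDIT3 (9.77 ± 0.306 to 47.7 ± 9.20 FPKM, adjusted p = 7.77e-05). Autophagy genes (4 of 19 higher and ATG7, chosen after its values were seen, lower; relative median 0.29, camera adjusted p = 0.0094, adjusted p = 0.168 with an estimated correlation) included MAP1LC3B and SQSTM1. The fall of ATG7 was not called without 0.4 µM replicate 2 or 0.8 µM replicate 2 or 3, nor after scaling to a common sum or median-of-ratios scaling, which left 0 lower. Of 20 immediate early genes 7 were higher and 2 lower, KLF2 and FOSL1 (relative median 0.47, camera adjusted p = 0.00755, adjusted p = 0.446 with an estimated correlation). The median of that list, not relative to all genes, was 0.38, and 0.20 without 0.4 µM replicate 1. The falls became 1 under each of the 3 other scalings and without any library except DMSO replicate 2 and 0.4 µM replicate 1, and without the latter 3.

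Lower at 0.8 than at 0.4 µM were 20 of 25 G2/M genes (22 when adjusted over the list alone; relative median −0.71, limma camera adjusted p = 2.62e-09, adjusted p = 0.168 with an estimated correlation), with CCNB1 at 168 ± 3.56 and 72.9 ± 6.28 FPKM and KIF2C at 45.5 ± 2.82 and 19.6 ± 3.37 FPKM. G1/S genes were lower in 12 of 23 cases and higher in 2 (relative median −0.22, camera adjusted p = 0.021, adjusted p = 0.381 with an estimated correlation), led by GINS1 and UNG. The list was not called after quantile normalization (relative median −0.13). The 12 became 7 under each of the 3 other scalings, 7 without 0.4 µM replicate 2 and 6 without 0.4 µM replicate 3 or 0.8 µM replicate 3, and the 2 became 1 without DMSO replicate 3, any 1 of the 0.4 µM libraries, or 0.8 µM replicate 1 or 2. Of 14 homologous recombination genes 7 were lower (relative median −0.22, camera adjusted p = 0.0094, adjusted p = 0.381 with an estimated correlation), and 4 without 0.4 µM replicate 3 or 0.8 µM replicate 3. Oxidative phosphorylation genes were lower in 16 of 30 cases (20 when adjusted over the list alone; relative median −0.26, camera adjusted p = 1.44e-05, adjusted p = 0.381 with an estimated correlation), and in 9 without 0.8 µM replicate 2. It was 10 of 30 after scaling to a common sum, 7 after median-of-ratios scaling and 9 after quantile normalization, where the relative median was −0.17. The list of ribosomal proteins (relative median −0.17, camera adjusted p = 0.0149, adjusted p = 0.674 with an estimated correlation) was not called without 0.4 µM replicate 1 (adjusted p = 0.165), 0.8 µM replicate 1 (0.118) or 0.8 µM replicate 2 (0.0591). It was not called after median-of-ratios scaling or after quantile normalization, where the relative median was −0.0072. Limma called 6 of its 30 members lower, 0 when adjusted over the list alone, 1 after scaling to a common sum or quantile normalization and 0 after median-of-ratios scaling. The 6 became 3 without DMSO replicate 1 or 0.8 µM replicate 3, 2 without DMSO replicate 2 or 3, 1 without 0.4 µM replicate 1 and 0 without 0.8 µM replicate 1 or 2. The list median, not relative to all genes, was −0.27, and −0.14 without 0.4 µM replicate 1.

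The other lists were not called between the doses. Of 27 NRF2 targets 4 were higher and 6 lower (relative median −0.11, but 0.01 after quantile normalization, where 3 were lower; limma camera adjusted p = 0.696), with ME1 higher (16.5 ± 0.290 to 30.1 ± 0.406 FPKM) and FTH1, the ferritin heavy chain gene, lower (888 ± 47.3 to 575 ± 33.9 FPKM). These counts moved to 1 higher without 0.4 µM replicate 2, 2 higher without 0.8 µM replicate 2 and 10 lower without 0.4 µM replicate 1. HMOX1 did not pass (620 ± 166 and 551 ± 168 FPKM, limma adjusted p = 0.62), nor did NFE2L2 (13.7 ± 1.00 and 14.7 ± 6.87 FPKM, adjusted p = 0.958; 0.0243 without 0.8 µM replicate 2), while KEAP1 was lower at 0.8 µM (31.6 ± 1.56 to 22.4 ± 1.0 FPKM, adjusted p = 0.00383). Apoptosis regulators were higher in 7 of 20 cases, among them BCL2L11 and TNFRSF10B, and lower in 4 (relative median 0.30, camera adjusted p = 0.0746). This list was called without 0.4 µM replicate 3 (adjusted p = 0.045) and without 0.8 µM replicate 1 or 2 (0.0438 and 0.0302). The 4 became 2 under each of the 3 other scalings and without 0.4 µM replicate 3 or 0.8 µM replicate 2 or 3.

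For the remaining lists between the doses, limma camera gave an adjusted p of 0.132 for ovarian carcinoma and epithelial markers (4 of 8 lower, and 2 after quantile normalization, among them PAX8 and KRT18 as deposited). It gave 0.167 for NF-kB targets and STAT3 targets, 0.201 for interferon-stimulated genes, and 0.24 for mitochondrially encoded mRNAs (relative median −0.19, but −0.51 after quantile normalization) and mesenchymal markers. Without 0.4 µM replicate 1 the mitochondrial list was called (median not relative to all genes −0.70, against −0.28 with all libraries, adjusted p = 0.0162), and without 0.4 µM replicate 3 the NF-kB list (in the same way 0.33 against 0.14, adjusted p = 0.0427). The value was 0.412 for hypoxia and glycolysis, 0.503 for proteasome subunits and YAP and TGF-beta targets, 0.759 for metallothioneins and fatty acid synthesis, and 0.85 for sterol synthesis. Relative median and test differed in sign for metallothioneins and fatty acid synthesis. The largest falls between the doses included INSYN2B (7.70 ± 3.09 to 1.04 ± 0.235 FPKM), F3 (105 ± 52.7 to 26.1 ± 4.20 FPKM) and PPP1R14B (188 ± 82.0 to 51.3 ± 20.1 FPKM). TUBB6, FAM83H, NUDT3, MTND1P23 and MT-TH also fell, each losing its call without at least 1 of the libraries compared. FAM83H did so without 0.8 µM replicate 1 (adjusted p = 0.0508), NUDT3 without 0.4 or 0.8 µM replicate 2 (up to 0.0605), and TUBB6 without any of these 6 libraries except 0.8 µM replicate 2 (up to 0.114). MTND1P23 did so without 0.4 or 0.8 µM replicate 2 or 3 (up to 0.0837), and MT-TH without 0.4 µM replicate 2 or 3 or 0.8 µM replicate 1 or 3 (up to 0.0841).

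Across genes, the log2 fold changes of both doses against DMSO had a correlation of 0.616, where unchanged groups sharing the same 3 DMSO libraries gave 0.502, and a covariance of 0.125 against a simulated 0.0268. The sign was the same in 74.0% of genes (66.6% simulated). Limma called 96 genes in the same direction at both doses, 55 higher and 41 lower, where independent lists would share 12.9 higher and 12.9 lower genes and unchanged groups with shared controls shared 0.01. In the simulation shared controls alone gave the covariance of 0.0268, which leaves 0.098 above it. The controls are too few to split, so their part was simulated and not measured on the libraries themselves, and genes are not independent replicates. Of the 96 shared calls 81 changed more at 0.8 µM. The number of shared calls ranged from 23 to 219 with 1 library left out. It was 25, 23 and 34 without DMSO replicates 1 to 3, 219, 35 and 47 without 0.4 µM replicates 1 to 3, and 47 and 42 without 0.8 µM replicates 1 and 3.

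A few genes changed at 0.4 µM and moved back at the higher dose. Among the 109 genes called at 0.4 µM, 15 differed between the doses in the direction of the DMSO level, and limma no longer called 12 of these against DMSO at 0.8 µM. Both comparisons use the same 0.4 µM libraries, so noise in these favours such a pattern. How many genes it would give was not computed. SNORD58B went from 19.7 ± 3.10 FPKM in DMSO to 0.131 ± 0.0158 at 0.4 µM and 23.9 ± 5.55 at 0.8 µM, ZNF672 from 8.51 ± 0.515 to 1.23 ± 0.514 and 10.4 FPKM, and C1GALT1C1, which encodes a chaperone of O-glycosylation, from 9.40 ± 1.19 to 1.49 ± 0.284 and 8.42 FPKM. SNORD58B is a small RNA lying within another gene, so its value is uncertain. Values of other single genes may be off as well. Across the libraries B2M had 1.05 to 3.28 FPKM and UBB 0.19 to 1.15 FPKM, which is low for such widely expressed genes. Whether reads were lost or misassigned for ZNF672 or C1GALT1C1 was not tested. Among the 6 NRF2 targets that were lower at 0.8 than at 0.4 µM were NQO1 (57.0, 149 and 102 FPKM) and FTH1 (498, 888 and 575 FPKM). Also highest at 0.4 µM was the hexokinase gene HKDC1 (7.66, 16.7 and 7.19 FPKM), which was chosen after its values were seen.

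**Figure D3:**
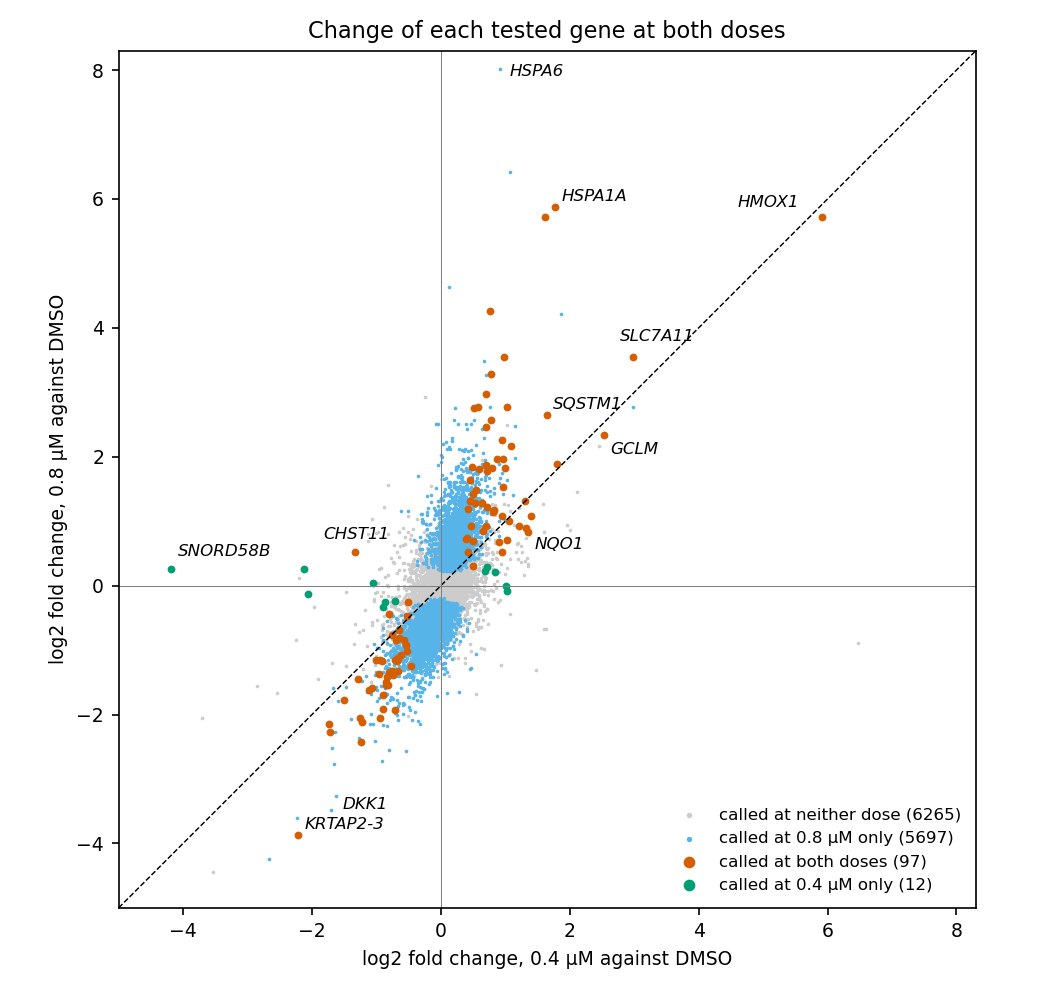
Log2 fold change against DMSO of each tested gene at 0.4 µM (horizontal) and 0.8 µM (vertical); colours mark genes called at both doses (97, of which 96 in the same direction), at 0.8 µM only (5697), at 0.4 µM only (12) or at neither (6265), and the dashed line marks equal change. Most genes called at both doses lie farther from 0 on the vertical axis.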

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

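Of the tests in this part, those for a wrong label, for dilution and for scaling, and the counts over other splits of the libraries, were chosen only after the result was seen. CHST11, which encodes a chondroitin sulfotransferase, was picked out because its changes at both doses against DMSO were called in opposite directions. It fell at 0.4 µM (log2 fold change −1.33, adjusted p = 0.00133) and rose at 0.8 µM (0.52, adjusted p = 0.00558). The difference of 1.85 between the doses follows from that choice, so no p-value is given for it. The gene went from 3.68 FPKM in DMSO to 0.868 and 5.70 FPKM, and the libraries of the 3 groups did not overlap. Its cause was not tested.

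The first pattern weighed is that 0.4 µM replicate 1 stood apart from the other libraries of its group, at −36.9 on the second principal component against 12.7 and 14.1. A wrong label within the study was argued against, because its mean over NRF2 targets lay 1.04 (log2) above the highest DMSO library, with a spread within groups of at most 0.0522, and its heat shock mean lay 1.92 below the lowest 0.8 µM library. Gene length bias stronger than in the other libraries was argued against as well. The correlation of its deviations with exon length, −0.248, lay within the −0.337 to 0.238 of the other 8 libraries. DMSO replicate 1 had −0.266 and 0.8 µM replicate 3 −0.337, so a length bias of this size is not excluded. The values of 0.4 µM replicates 2 and 3 were taken against means that include this library. The correlation with GC content for this library, 0.290, lay outside the −0.274 to 0.224 of the others. Dilution with RNA of untreated cells cannot be told apart from other causes. The median change in this library was 0.698 of that in the other libraries of its group (interval 0.535 to 0.814). This ratio was also under 1 for replicates 2 and 3 (0.888, 0.808 to 0.996, and 0.812, 0.764 to 0.897), and the intervals overlap. They come from resampling genes and do not measure the spread between libraries. The genes were called without the library in question, which favours a smaller change in it. Of 238 genes called without this library, 154 changed less in it than in both others and 70 changed more. Dilution alone would not move genes farther from DMSO except through noise, and no spread of these counts was computed. So dilution as part of the cause, GC bias and length bias stay open, as does a dose or time other than the stated one. No biological explanation was tested.

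The next pattern is that genes of oxidative phosphorylation, cytosolic ribosomes and mitosis were lower at 0.8 µM than in DMSO, while fold changes across genes correlated with exon length (0.285) and GC content (−0.227). With the trend with exon length removed, the medians were −0.36, −0.26 and −0.50. With the trend with GC content removed they were −0.43, −0.35 and −0.65. Exon length here sums all annotated exons of a gene, and its median was 3150, 3759 and 3815 bases for these lists and 4621 for all genes. The values argue against the trend with GC content, and with exon length so defined, as the whole cause. A bias with the length of the mRNA expressed was not tested, nor was a trend of the fold change with expression level. With a filter at FPKM 5, the median of all genes at 0.8 µM was −0.169, against −0.0669 in the main run. Medians relative to all genes do not remove such a trend. Among 4 scalings, the median relative to all genes stayed at −0.28 or lower for oxidative phosphorylation and at −0.39 or lower for mitosis. A common sum and median-of-ratios scaling multiply each library by a single factor, which nearly cancels in a median relative to all genes. Only quantile normalization could move that median much, so these values argue against scaling only for the fall relative to all genes. How far these lists fell in absolute terms stays open to scaling. For ribosomal proteins the relative median came as near to 0 as −0.0232 under quantile normalization, so scaling between libraries is a candidate explanation of that fall. For the other lists a response to the compound may be the cause, which is a hypothesis, since it was found and tested on the same libraries.

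The last pattern is that genes named ZNF, most of them for zinc finger transcription factors, were higher at 0.8 µM than in DMSO, with 132 of 300 tested genes rising and 28 falling. It was noticed in a scan of 197 families of symbols with at least 8 tested members, so it was picked for its size. The median was 0.34 with the trend with exon length removed and 0.32 with the trend with GC content removed. These values argue against either trend as the whole cause, but a bias with the length of the mRNA expressed was not tested. A trend with expression level was not tested either, and the median of all genes was lower with a filter at FPKM 5. The median relative to all genes was at least 0.35 under 4 scalings, of which mainly quantile normalization could move it. This argues against scaling only for the rise relative to all genes. With each library left out in turn, 92 to 143 rose. A response to the compound may be the cause, as a hypothesis only, and a slower decay or a faster synthesis of such mRNAs was not measured here.

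For other splits of the 6 libraries of a comparison into 2 groups of 3, there are 10 splits, too few for a share under 0.05. The real splits gave 109, 5794 and 4212 genes for 0.4 µM against DMSO, 0.8 µM against DMSO and 0.8 against 0.4 µM, and the highest other splits 11, 2 and 2, so that 1 of 10 splits gave as many in each. For gene lists called by limma camera, the real splits gave 10, 11 and 10 and the highest others 11, 13 and 12, and 3, 4 and 5 of the 10 splits gave as many. Each other split puts libraries of both real groups on each side. A real difference then adds to the spread and also remains in part between the sides. The counts of the other splits are therefore not those of unchanged groups, and no conclusion is drawn from them.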

How the results depend on the processing

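All settings in this part were planned, except the counts of list members without single libraries, which were tests chosen only after the result was seen. Of the 109 genes changed at 0.4 µM, the number was 70 with no filter, 27 in a fit to the 6 libraries of the groups compared, 23 at an adjusted p under 0.01 and 34 at 2-fold or more, and it ranged from 31 (without DMSO replicate 1 or 2) to 238 (without 0.4 µM replicate 1). With the replicate number as a block it was 29, and the calls shared between the doses, 96 in all, were 24. These shared calls numbered 61 with no filter, 21 with 6 libraries, 18 at an adjusted p under 0.01 and 23 at 2-fold or more, and ranged from 23 (without DMSO replicate 2) to 219 (without 0.4 µM replicate 1). For 0.8 µM against DMSO, the 5794 genes were 3589 with a filter at FPKM 5, 3812 at an adjusted p under 0.01 and 1013 at 2-fold or more. Between the doses, 4212 became 2078 and 435 under these thresholds, and 2713 (without 0.8 µM replicate 2) to 4063 (without 0.4 µM replicate 1). Stricter thresholds lower such counts by construction, and for the other settings the cause was not tested.

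The number of lists called depended most on how the correlation between genes was treated. From 10, 11 and 10 lists, an estimated correlation in limma camera left 2, 0 and 1, with 4, 6 and 5 lists at an unadjusted p under 0.05, and limma fry in place of camera gave 6, 20 and 15. Limma fry ended 6 of the 10 list calls at 0.4 µM, and a filter at FPKM 5 ended 3 of the 10 between the doses. Of the called lists, 2 of 10, 0 of 11 and 1 of 10 were called in all alternatives, and 7, 11 and 9 with each library left out. Of the named genes called, 12 of 23, 97 of 105 and 71 of 101 were called in all alternatives. Over all alternatives of the named genes, 4469 values kept direction and call and 326 lost the call. A change of sign was seen in 15, and 1 kept its direction and gained a call. Among those that changed sign, NFE2L2 between the doses was also called, without 0.8 µM replicate 2. The correlation between the doses was 0.616 and ranged from 0.556 to 0.636 over the alternatives. Its jackknife error of 0.0789 comes from the same runs with 1 library left out, so it is no separate check on that range.

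The values that changed sign belonged to genes that were not called. STAT3 at 0.4 µM (−0.02) was 0.0348 when scaled to a common sum and ranged from −0.0778 to 0.0741 with a library left out. DDIT3 at 0.4 µM (0.03) was −0.0078 with median-of-ratios scaling and ranged from −0.0444 to 0.13. NFE2L2 between the doses (−0.03) was 0.0040 with pseudocount 5, 0.0494 with a common sum, 0.0861 with median-of-ratios scaling and 0.0817 with quantile normalization. It ranged from −0.29 (without 0.8 µM replicate 1) to 0.41 (without 0.8 µM replicate 2, the one call among its alternatives, adjusted p = 0.0243, against up to 0.991 in the others). HMOX1 between the doses (−0.18) was 0.0079 with quantile normalization and ranged from −0.40 to 0.041. Limits of the design are 3 libraries a group, FPKM in place of counts, and no statement that libraries of a group came from separate cultures.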

Other observations

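The families of this part were noticed in the same scan as the ZNF genes, so their counts and tests, and the genes named in them, were chosen only after the result was seen, and no test was run on a family as a set. Mitochondria make a few respiratory proteins on ribosomes of their own, whose proteins are encoded in the nucleus. Of 52 tested genes named MRPL, for the large subunit of these ribosomes, 36 fell and 2 rose at 0.8 µM against DMSO, with a median relative to all genes of −0.52 (−0.57 to −0.44 under 4 scalings). MRPL12 fell from 169 ± 15.8 to 65.5 ± 13.7 FPKM (limma adjusted p = 0.000372) and MRPL15 from 78.8 ± 6.78 to 34.0 ± 1.39 FPKM (adjusted p = 0.000113). MRPL18 went the other way, from 36.6 ± 1.37 to 129 ± 20.4 FPKM (adjusted p = 6.89e-05). With each library left out in turn, 29 to 36 fell, and 1 rose without any 1 DMSO library, 0.4 µM replicate 2 or 3, or 0.8 µM replicate 3.

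Keratins form the filaments of epithelial cells. Of 17 tested entries named KRT, 16 fell at 0.8 µM (relative median −1.03, −1.03 to −0.87 under 4 scalings), and 12 to 16 fell with each library left out. KRT7 went from 169 ± 3.91 to 77.2 ± 18.4 FPKM and KRT8 from 300 ± 16 to 171 ± 27.3 FPKM (limma adjusted p = 0.000489 and 0.000848). Some entries are KRT8 pseudogenes, whose reads cannot be separated from those of their parent gene. At 0.4 µM 2 of the 17 fell (relative median −0.64), but none did so by limma without any 1 DMSO library or 0.8 µM replicate 1, 1 did without 0.4 or 0.8 µM replicate 2 or 3, and 6 did without 0.4 µM replicate 1. Of 15 lysine demethylase genes named KDM, which act on chromatin, 12 rose and 1 fell at 0.8 µM (relative median 0.64, 0.63 to 0.65 under 4 scalings), and 8 to 12 rose with each library left out. KDM2A went from 7.33 ± 1.5 to 21.1 ± 1.79 FPKM and KDM5A from 2.25 ± 0.359 to 7.07 ± 0.924 FPKM (adjusted p = 0.000138 and 9.22e-05), while KDM1A fell from 26.3 ± 1.18 to 20.6 ± 1.28 FPKM (adjusted p = 0.00798).

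In the library that stood apart, some genes at 0.4 µM were nearer to the level of the higher dose, and TXNRD1 was nearer to that of DMSO. SERPINB2 had 0.861 FPKM in 0.4 µM replicate 1 against 10.2 and 11.7 in the other libraries of its group, and 1.35 to 1.65 at 0.8 µM. DKK1 had 7.04 against 23.8 and 26.8. TXNRD1 had 44.9 against 244 and 265, and 17.1 to 17.5 in DMSO. So SERPINB2 and DKK1 lay farther from DMSO in this library than in the others of its group, and TXNRD1 lay nearer. These genes were chosen because they stood out, and the counts over all 238 genes called without this library, 70 of which changed more in it, are given with the dilution weighed above.

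Other genes that changed at 0.4 µM and moved back towards DMSO at 0.8 µM were CBR3, FAM83A, COPS7B, ACTR3 and SFT2D1, all chosen after their values were seen. The limit of shared 0.4 µM libraries applies to them as well. FAM83A went from 6.56 to 2.69 and 6.76 FPKM, and COPS7B from 3.62 to 8.21 and 3.53 FPKM, in DMSO and at 0.4 and 0.8 µM. A ribosomal RNA clone in the table, FP236383, also chosen after its values were seen, ranged from 975.3 to 13898 FPKM across the 9 libraries, with both extremes in treated libraries. Within the 0.4 µM group alone it ranged from 1408 to 13898 FPKM.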
